A study of Cereibacter sphaeroides 2.4.1 with 2 samples.

How the data were processed

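Total RNA of 2 strains of the photosynthetic bacterium Rhodobacter sphaeroides 2.4.1 was compared on 2 two-colour Agilent arrays. Per the labels' protocols, both strains were grown with air and exposed for 10 min to 0.2 µM methylene blue, a dye that forms singlet oxygen in light, and to white light of 800 W per m2. RNA was isolated with hot phenol, treated with DNase I, cleaned on columns and labelled chemically with a ULS kit, which attaches the dye to the RNA itself. On each array, RNA of the strain that overexpresses the small RNA SorY carried Cy3 and RNA of the strain with the empty vector carried Cy5. The labels tie array 1 to biological samples 1 to 3 and array 2 to samples 4 to 6, and they do not say whether these were pooled. Both arrays have the same dye orientation and come from 1 slide and 1 scan.

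The deposited scanner files hold intensity values: per the file headers, Agilent Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09 gave a median spot signal and a median local background for each channel. The same deposited files hold processed intensity values, which per the file headers are background subtracted, detrended and dye normalized. They also hold a log10 ratio of red over green and other columns of flags for spots that are well above background, saturated or outlying, per the file headers. The authors' deposited value table holds log2 ratios, and limma is named for it in the submitters' processing notes, with no version given. Its scale and direction were found from the values: in both columns, 15208 of 15208 values equalled the loess-normalized log2 ratio of Cy3 over Cy5 without background correction, to a tolerance of 1e-06. The medians of its columns were 0.0043 for array 1 and 0.0021 for array 2.

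The analysis was made with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50. The design had named mean signals, but the columns used here were median signals, so medians took their place. Ratios were normalized within each array by loess with a span of 0.3 and control spots at weight 0. No spot carried an outlier flag or was saturated. Spots of a probe were averaged, probes were kept when well above background in 1 or more channels on each array, and probes of a feature were averaged as log2 ratios. Of 13218 probes, 13126 were kept and 92 were dropped. Log2 ratios are given as SorY strain over empty vector throughout.

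The 4516 features were 4372 genes with a numeric ID and 144 features with a readable name. The latter cover intergenic regions, antisense strands, gene ends and small RNAs, and each is the mean of 1 to 3 probes. The files do not pair the numeric IDs with gene names. None of the IDs matched the reference table of assembly ASM332471v1 (0 of 4372), and that table held 0 locus tags of the older RSP series. The 21 gene lists fixed before the data were examined, on transport, stress defence, photosynthesis and other functions, therefore had no measured members that could be recognised (0 of 21 lists), and takP, the transporter gene linked to SorY, has no value here. In their place, 7 groups of readable names were fixed after the names and before the values were seen.

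Each feature's mean log2 ratio was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. With 2 arrays there was 1 residual degree of freedom per feature, and the prior had 5.51. The p-values of single features measure only the spread between these 2 arrays, which share a slide and a dye orientation. Groups of features were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the 6 groups of 3 or more members. That test compares members with all other features, so its p-values do not measure the spread between arrays. With an estimated correlation, camera uses the residual degrees of freedom, 1 here, so that test could hardly pass. The rule for named genes, written before the data were examined, took SorY and takP in any case, the 12 highest and 12 lowest genes among those past the threshold with one sign on both arrays, and up to 4 members of each fixed list. Because IDs have no names, 2 IDs that rose and 2 that fell are printed. The rule kept intergenic probes to a count, so every feature with a readable name other than the SorY region that is named was chosen after the values were seen, except the members of the small RNA groups.

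The test was tried on simulated data. In 20 simulations of 4516 features without a dye effect, all of the features changed by log2 0.5 or by 1 were recovered (100%), and on average 7.13% of calls were unchanged features, with a highest value of 15.6%. The prior degrees of freedom varied from 3.90 to 19.9 in these simulations. When a probe effect shared by both arrays was simulated on 4196 genes with 3 probes, the test called 69.1% of the unchanged genes. A test on the spread over the 3 probes of a gene called 0.15% of them. The simulated probe effects were independent of each other, as that test assumes, so its low share was built in.

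Alternatives fixed before the data were examined changed the background correction, the normalization within arrays, the filter on dim probes, the summary of probes, the variance model, the unit tested, the size threshold and the group test, and left out each array in turn. Alternatives chosen after seeing the data were the spread over probes as the error, a loess span of 0.1, leaving out a separate number series of IDs, and groups without the SorY region. A correction for base composition was not run because probe sequences were not used here. Median signals were 4079 (Cy3) and 6726 (Cy5) on array 1, and 5185 and 6121 on array 2. The number of arrays limits the precision.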

Results

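The data set compared a strain of Rhodobacter sphaeroides 2.4.1 that overexpresses the small RNA SorY with a strain carrying the empty vector, both after 10 min of singlet oxygen stress. Each of 2 arrays held both strains, the SorY strain in Cy3 and the vector strain in Cy5. The question was which transcripts differ in level when SorY is overexpressed during photooxidative stress. Between 98.7% and 99.5% of spots were well above background in each channel. The log2 ratios of the arrays correlated with Pearson's r = 0.96 and Spearman's rho = 0.96 across 4516 features, which are not independent replicates. The difference between the arrays was itself shared by probes of one gene, with an intraclass correlation of 0.21 against at most 0.034 in 200 shuffles within signal bins. The arrays were treated as 2 samples because the labels give them different biological samples.

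The region that holds SorY was higher in the SorY strain. SorY, also known as RSs1543, is a small regulatory RNA made under singlet oxygen stress, and the array carried 1 probe for the sense strand of intergenic region IGR_1543, from position 1632533 to 1632899 in the probe's name, with the replicon and genome build not given there. This match rests on the shared number. Its log2 ratio was 1.58 on array 1 and 1.42 on array 2, a mean of 1.50 ± 0.11 (SD, n = 2 arrays), or 2.83-fold (limma, adjusted p = 3.7e-06). The size depended on the normalization: the log2 ratio was 0.43 with median centring and 2.09 with a loess span of 0.1, with the call kept in both. It ranked 10 among all features in mean signal, and 15 of the 16 other features outside a series of 54 bright IDs in the same signal range were lower, with a median of -0.69.

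**Figure D1:**
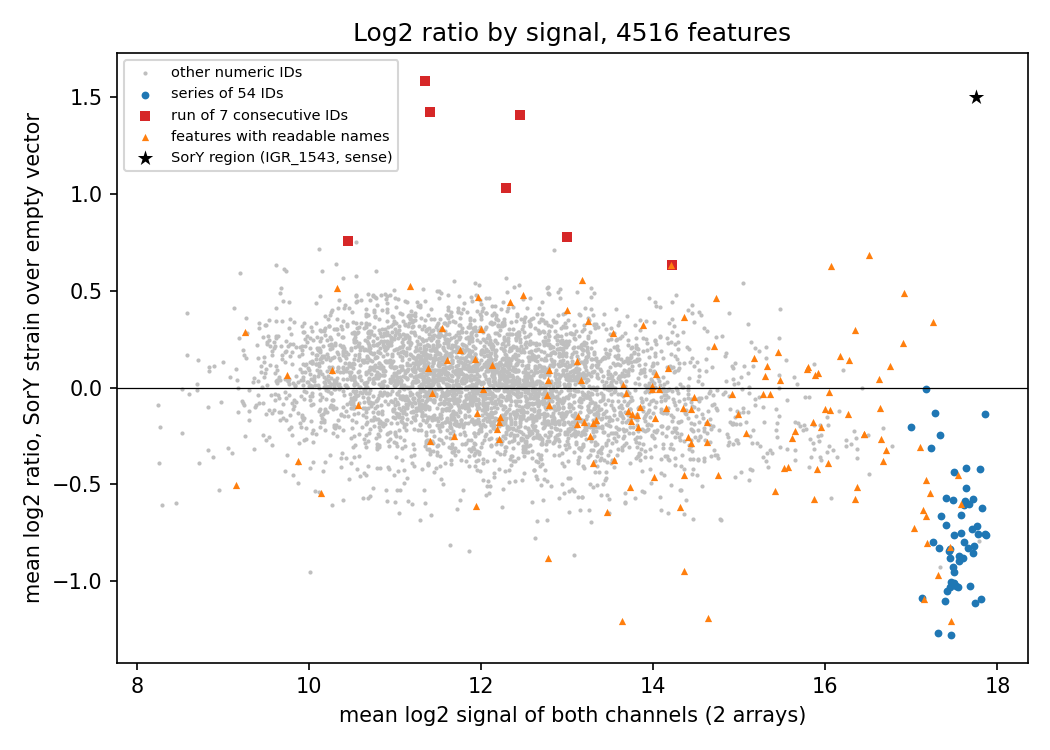
Mean log2 ratio of the SorY strain over the empty vector (y axis) against mean log2 signal of both channels (x axis) for 4516 features, each point the mean of 2 arrays. The SorY region stands at 1.50 among the brightest features, most of which lie below 0, and the run of 7 consecutive IDs lies between 0.63 and 1.59 at moderate signal.

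The largest rise outside the SorY region was in a run of 7 genes with consecutive IDs. Their mean log2 ratios lay between 0.63 and 1.59, with a median of 1.03, and each passed the test on 2 arrays. A run was counted over IDs past the threshold at 0.5 or more. The IDs just before and just after it were also above 0, at 0.46 and 0.39, so its ends depend on that bound. The IDs with the highest ratios were 640070755, at 1.59 ± 0.31 (SD, n = 2 arrays; 3.00-fold; limma, adjusted p = 2.2e-05), and 640070754, at 1.43 ± 0.25 (2.69-fold; limma, adjusted p = 1.7e-05). All 21 probes of the run were above 0, from 0.38 to 1.69. Array 1 gave the higher value for 7 of the 7 genes. The size depended on the background correction: without it, 640070755 was at 1.09, 640070754 at 0.99 and the median of the run at 0.83. That median was also 0.83 in the deposited values. It was 1.07 with processed signals, 1.01 with median centring and 1.03 with a loess span of 0.1. What these genes encode is not paired with their IDs in the files.

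**Figure D2:**
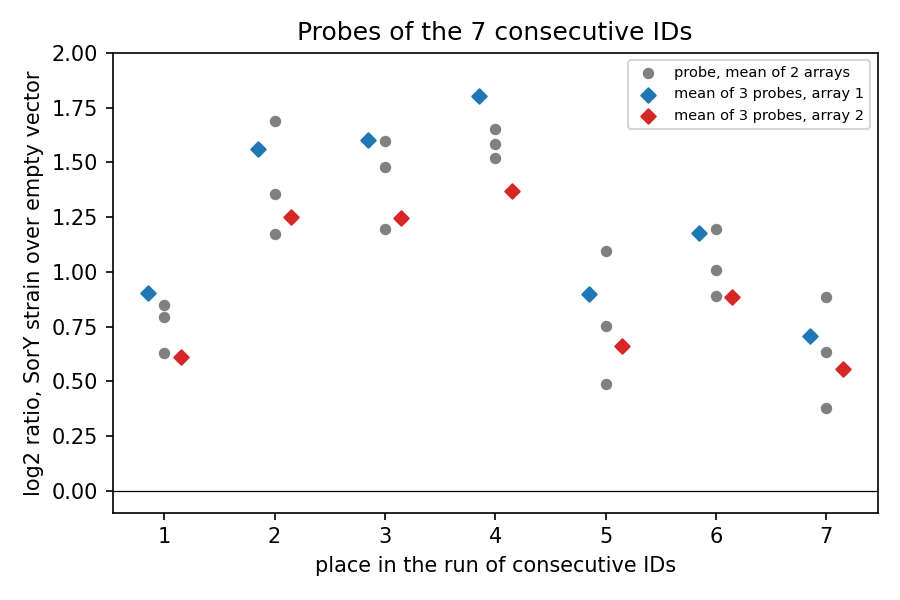
Log2 ratio of the SorY strain over the empty vector (y axis) for the 7 consecutive IDs in order (x axis), with grey points for each probe averaged over 2 arrays and diamonds for the mean of 3 probes on each array. All 21 probes lie above 0.

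The genes with the lowest ratios belonged to a separate number series of 54 IDs. In this series 53 IDs were lower and passed the test, 1 did not pass, and none was higher (0 of 54). The median log2 ratio was -0.83 on array 1 and -0.74 on array 2. ID 640710021 was lowest, at -1.28 ± 0.19 (SD, n = 2 arrays; limma, adjusted p = 1.3e-05), followed by 640709966 at -1.27 ± 0.059 (limma, adjusted p = 3.7e-06). All 54 were among the 90 brightest features, and 46 of them had 1 probe. The median of the series was -1.80 with median centring, -0.58 with Agilent's processed signals and -0.25 with a loess span of 0.1.

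Among the stress-induced small RNA regions, only the SorY region was higher and past the threshold. In the group of stress-induced small RNA regions, which holds 6 members with SorY and 3 probes of IGR_0680 among them, 1 was higher, 3 were lower and 2 did not pass, the same counts as adjusted over the list alone. IGR_2461 (sense) was at -0.51 ± 0.017 (SD, n = 2 arrays) and IGR_0019 (sense) at -0.26 ± 0.067. The 3 probes of IGR_0680 (antisense) differed between the arrays: IGR_0680b was -0.12 on array 1 and 0.25 on array 2, and IGR_0680c was -0.057 and 0.34, neither past the threshold, while IGR_0680a passed at a mean of -0.24, from -0.45 on array 1 and -0.025 on array 2. IGR_0680b turned to -0.39 and IGR_0680c to -0.44 with median centring. With a loess span of 0.1, IGR_0019 was at -0.065 and IGR_0680a at -0.11, neither past the threshold. IGR_0680c passed as higher at 0.20 with that span. It also passed with the median of probes, but with 1 probe its value of 0.14 was that of the main test. That pass rested on a changed error estimate: the SorY region, at an unchanged 1.50, went to 1.8e-244 (limma, adjusted p). IGR_2461 was at -1.12 and IGR_0019 at -0.79 with median centring, and at -0.31 and -0.15 with Agilent's processed signals. The group median was -0.087 and its mean 0.12, opposite in sign, and the group did not pass (camera, adjusted p = 0.72). With median centring the median was -0.61 and the group passed (camera, adjusted p = 0.035). The median was -0.22 on array 1 and 0.11 on array 2. These values count the SorY region, which is overexpressed by construction: the 5 other members had a median of -0.24 and a mean of -0.16, with medians of -0.31 on array 1 and -0.025 on array 2, and did not pass (camera, adjusted p = 0.35). With SorY counted, the median stood at the 96.95 percentile of 10000 random lists matched on mean signal, whose medians centred on -0.33. No percentile was computed without SorY. Matched lists, here and for the other groups, could draw on the series of 54 bright IDs and were not matched on the number of probes per feature. The 90 brightest features had a median of -0.66, and of -0.34 without the 54 IDs, so the matched medians of bright groups partly repeat that series.

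In the group of other small RNA regions and RSsh probes, 6 of 8 members fell, 1 rose and 1 did not pass, with a median log2 ratio of -0.40 (camera, adjusted p = 0.039). The call of the group was lost with an estimated correlation (adjusted p = 0.67), with processed signals (adjusted p = 0.35) and with a loess span of 0.1 (adjusted p = 0.22), while with median centring the median was -0.88 (adjusted p = 0.00012). IGR_0682 (sense, 694011 to 694910) fell most, to -1.09 ± 0.072 (SD, n = 2 arrays), followed by IGR_1386 (antisense) at -0.63 ± 0.24 and RSsh1 at -0.61 ± 0.12. IGR_1368 (antisense) was the member that rose, to 0.11, and it was at -0.62 with median centring, 0.49 with processed signals and 0.36 with a loess span of 0.1. With Agilent's processed signals IGR_1386 was at -0.087 and did not pass. The member that did not pass in the main test, IGR_2778 (sense) at 0.038, passed at 0.092 with processed signals. IGR_0682 was at -1.95 and IGR_1386 at -1.49 with median centring, and at -0.71 and -0.25 with a loess span of 0.1. Lists matched on signal, which could draw on the series of 54 bright IDs, had a median of -0.36. The group median stood at the 43.25 percentile of these lists, so the group was about as low as features of like signal.

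**Figure D3:**
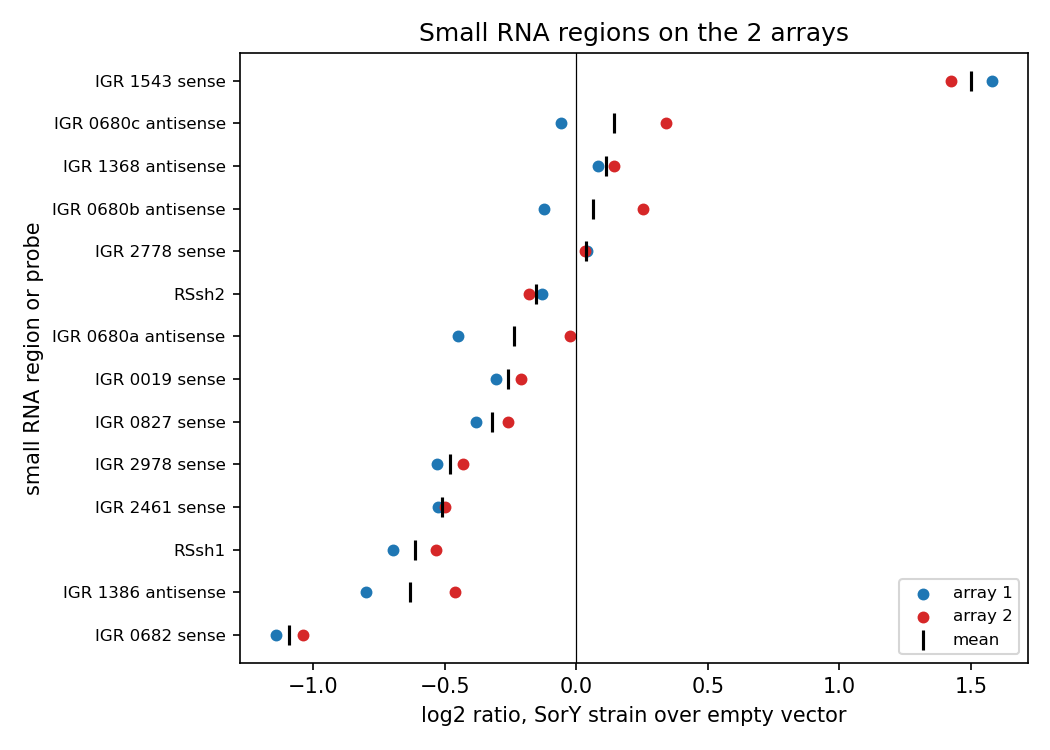
Log2 ratio of the SorY strain over the empty vector (x axis) for the regions and probes of the small RNA groups (y axis), with a point for each of 2 arrays and a bar for the mean. The SorY region (IGR_1543) is at 1.50, and IGR_0682 is lowest at -1.09.

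Intergenic features were lower on balance on both strands, but no lower than random lists matched on mean signal. The test with a preset correlation called both groups, and neither call held with an estimated correlation (adjusted p = 0.67 in both) or with a loess span of 0.1 (adjusted p = 0.096 and 0.19). The estimated correlations were -0.0029 (sense) and 0.0071 (antisense). With 1 residual degree of freedom they rest only on which array was higher for each member, so they hardly measure how members vary together. The higher p of that test likewise does not show that members were correlated. With median centring the medians were -0.33 (sense) and -0.34 (antisense), and with processed signals the antisense call ended at a median of -0.086 (adjusted p = 0.35). Both groups also count the intergenic members of the small RNA groups, so the calls of these groups are not separate. Of 59 sense features, which include the SorY region, 14 rose, 38 fell and 7 did not pass. Their median log2 ratio was -0.18 (camera, adjusted p = 0.0033). Of 48 antisense features, 10 rose, 25 fell and 13 did not pass, with a median of -0.13 (camera, adjusted p = 0.039). On array 2 alone the antisense median was -0.058. The medians of 10000 random lists matched on mean signal centred on -0.18 for the sense group and -0.13 for the antisense group. The group medians stood at the 50.03 percentile (sense) and the 50.94 percentile (antisense) of these lists. IGR_0552 (sense) was at -1.21, IGR_0042 (antisense) at -1.20, IGR_2363 (sense) at -0.97 and IGR_0703 (sense) at -0.95. IGR_0552 was at -2.17 and IGR_2363 at -1.89 with median centring, and at -0.71 and -0.53 with a loess span of 0.1. IGR_1943 (antisense) was at 0.68 while its sense probe was at 0.065, and the antisense value was 0.033 and no longer past the threshold with median centring.

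Features antisense to named genes went both ways. Of 23, 13 rose, 9 fell and 1 did not pass, with a median log2 ratio of 0.15 (camera, adjusted p = 0.46), which was -0.023 with median centring. The median stood at the 99.98 percentile of 10000 random lists matched on mean signal, whose medians centred on -0.059 and reached 0.15. The lists were not matched on the number of probes, and most of the 23 had fewer than 3 while most IDs had 3. The medians of the lists may therefore vary too little, and the percentile may be overstated. The probe asRSP3018_No1 was at 0.64 and asRSP3616 at 0.63, while asRSP3619 was at -0.58. With median centring asRSP3616 was at 0.12. The other probe of the first gene, asRSP3018_No2, was at -0.087. Of 11 features for gene ends, 5 rose, 4 fell and 2 did not pass. Their median of -0.027 (camera, adjusted p = 0.72) was -0.060 on array 1 and 0.017 on array 2. It was 0.15 with processed signals and -0.20 with median centring. The 3' probe of RSP0019 was lowest at -1.19 ± 0.015 (SD, n = 2 arrays).

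Over all features, 3446 of 4516 passed the test, 1769 higher and 1677 lower, or 76.3%. Most of these differences were small: 2221 were under 0.25 in absolute log2 ratio, and 192 were 0.5 or more. On both arrays, 4 features had a log2 ratio of 1 or more and 9 had -1 or less, where independent arrays with the same shares would give 0.0044 and 0.049. The arrays share a slide and a dye orientation, so a shared probe or dye effect would also exceed these values. Array 1 alone gave 17 at -1 or less, median centring gave 73 on both arrays, and a loess span of 0.1 gave 2. Without background correction, 2 features had 1 or more on both arrays and 15 had -1 or less. Probes of one gene differed more than the arrays did. For 4196 genes with 3 probes, the SD between probes of a gene was 0.20 and the SD between arrays of one probe was 0.066, and 35.1% of the genes that passed had probes on both sides of 0. With the spread over the 3 probes as the error, 207 of these genes passed, 70 higher and 137 lower. The 3 probes measured the same RNA, so this error does not measure the spread between RNA samples. All 207 had also passed on the spread between arrays, which called 3175, or 75.7%, so this overlap says little. With the channels as unpaired groups, 1570 features passed. Because the dyes were not swapped, a dye effect and a difference between the strains are not separated in any of these ratios.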

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

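Positive control probes, which the comparison of the strains leaves out, gave signal above every negative control spot in both channels on both arrays for 43 of 57 probes. No explanation was tested.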

How the results depend on the processing

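The loess span of 0.1, the spread over probes and the omission of the series of 54 IDs or of the SorY region were chosen after seeing the data. The SorY region stayed higher and past the threshold in all 9 alternatives with a test, from 0.43 to 2.09, and at 1.42 to 1.58 with either array left out. Not all 9 were separate checks. With 1 bright probe, its value of 1.50 could not move with the filter on dim probes or the median of probes. The deposited values repeat the setting without background correction, at 1.40 in both. The total of 3446 stayed within 1.5 times under the other alternatives than these: no replicate block, with the channels unpaired, gave 1570 (749 higher, 821 lower); probes in place of genes gave 9621 (4909 and 4712); the spread over 3 probes gave 207 (70 and 137), among fewer genes. Features at 1 or more on both arrays numbered 2 without background correction and 2 in the deposited values, and those at -1 or less 15 and 15. Features at -1 or less were 73 with median centring and 2 with a loess span of 0.1; a size of 0.65 gave 10 and 56. One array alone gave 4 to 5 at 1 or more and 13 to 17 at -1 or less.

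The agreement of arrays was 0.970 without background correction and 0.970 in the deposited values, 0.945 with processed signals, 0.960 with an offset of 0, 0.980 with median centring, 0.949 with the median of probes and 0.957 with a span of 0.1. With processed signals, other small RNA regions were at -0.12 and antisense intergenic features at -0.086, neither past the threshold, and IGR_0680b at -0.024. With median centring, stress-induced regions were at -0.61 and passed, antisense to named genes was -0.023, gene ends -0.20, 3'RSP3584 -0.29, IGR_0680b -0.39, IGR_0680c -0.44, IGR_1368 -0.62 and IGR_2778 -0.0012. With a span of 0.1, stress-induced regions were at -0.0071, with the test direction turned. Other small RNA regions were at -0.13, sense intergenic features at -0.11 and antisense ones at -0.097. None of these groups was past the threshold at that span. The median of probes and fry turned the test direction of stress-induced regions at a median of -0.087, and fry that of gene ends at -0.027. An estimated correlation and fry ended the calls of other small RNA regions (-0.40), sense (-0.18) and antisense (-0.13) intergenic features. One array alone gave sense -0.20 to -0.18, antisense -0.14 to -0.058, antisense to named genes 0.10 to 0.13, stress-induced regions -0.22 to 0.11 and gene ends -0.060 to 0.017, the last 2 with a change of sign (SorY counted among the stress-induced regions). The causes were not tested. A loess on base composition was not run. At least 98.7% of spots were well above local background, but negative control spots had medians of 1158 to 1530 against median signals of 4079 to 6726, which limits dim features.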

Other observations

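The tests on agreement between probes and arrays, on swapped dyes, on intergenic groups beside the series of 54 IDs, on the probes of the run of 7, on shuffled probes and on the closer of 2 signal matchings were chosen after the result was seen.

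Genes with consecutive IDs tended to share their log2 ratio. Outside the run of 7, the correlation across 4068 pairs of consecutive IDs was 0.46, against at most 0.061 in 10000 permutations, and it fell to 0.32 at a step of 2, 0.14 at a step of 5 and 0.013 at a step of 50. These pairs are not independent replicates. Another 6 consecutive IDs were lower together, from -0.70 to -0.51, and 4 others from -0.86 to -0.59.

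Log2 ratios agreed closely between the arrays and 76.3% of features passed the test. The share of the reproducible variance that lay between probes of one gene was 0.51, so a dye effect of single probes may account for part of it, as could real differences along a transcript. As the whole cause, a dye effect that varies independently between probes is argued against by the intraclass correlation of 0.48 between probes of one gene. Both values come from the same split of the variance, so they are not separate tests. With 0 arrays with swapped dyes, a difference between the strains cannot be told apart from a dye effect common to all probes of a gene.

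The series of 54 IDs was lower in the SorY strain, with a median of -0.78. Having 1 probe as the cause is argued against by the 6 IDs of the series with 3 probes, which were also lower, from -1.11 to -0.84. The 15 other ID features with 1 probe had a median of 0.091, but they were not matched on signal. A drop shared with intergenic RNA stays open. The lowest median of the intergenic groups was -0.18, with an SD of 0.41 between members, but these groups were dimmer. In the signal range of the series, 13 of 13 intergenic features other than the SorY region were lower, with a median of -0.66. High signal could be a technical source, and the tests of it came apart: the median of -0.78 lay below the lowest of 10000 lists matched in 50 equal bins of signal (-0.62), the matching used for all groups, but within those matched to 0.25 log2 of each member (-0.82 to -0.45), a closer matching. In the bins, the 37 other features were dimmer, with a median log2 signal of 16.9 against 17.5, and the closer matching drew on 21 features. High signal, a drop shared with intergenic RNA and a difference between the strains therefore cannot be told apart for these IDs.

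The run of 7 consecutive IDs was higher in the SorY strain. That 21 of 21 probes lie above 0 decides nothing, since the run was picked by its high means. For single probes that vary independently of their gene, probes were shuffled among genes: 0 of 1000 shuffles gave 7 consecutive IDs at 0.5 or more. The longest run had 2. Shuffling breaks the agreement between probes of one gene, which over all genes with 3 probes had an intraclass correlation of 0.48. It also breaks the agreement between consecutive IDs, so it decides nothing about the cause of this run. A candidate explanation is that genes with consecutive IDs are transcribed together, in line with the correlation of 0.46 over the other IDs, although the files do not say that consecutive IDs are neighbouring genes. An effect of SorY on this run, or a dye effect common to all probes of a gene, stays untested, since the dyes were not swapped.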
